A study of Mus musculus with 2 samples.

How the data were processed

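H3K4me1 ChIP-seq was carried out on hindbrain dissected from mouse embryos at 12.5 days. The labels give 1 group of 2 biological replicates, from pools of 120 and 88 embryos, and fragments of 300 to 500 bp. Replicate numbers were taken from the labels.

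The peak lists are deposited in narrowPeak format on the mm10 build, per the labels. Per the labels, peaks were called for each replicate alone and for both replicates pooled, and the replicated list derives from the pooled list and both replicates' lists. The list of replicate 1 derives from its alignment and 2 control files, and that of replicate 2 from its alignment and 1 control file, per the labels, so the lists differ in processing as well as in sample. The peak caller, the aligner and their versions are not given in the sources used here. Each peak has a deposited score from the authors, which was not used for any result. The authors also give a fold enrichment over control, a linear ratio, and a deposited −log10 p-value and −log10 q-value. The −log10 p-value was used only to order peaks of equal fold enrichment within a replicate's list. The deposited summit offset of each peak, in bp, was not used. These values belong to single peaks and served only to describe, rank or filter peaks within a list. Peak names carry a rank, and the ranks were without gaps in both replicates' lists and in the pooled list. Read numbers were not given in the files used here, so the depth is unknown and no counting error of reads could be given. The binomial intervals computed for shares of peaks are not intervals of biological spread.

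Genes came from the GENCODE mouse annotation, release 21, and sequence from the matching GRCm38 assembly. No peak lay past the end of a chromosome, and between 1 and 3 peaks per list touched an assembly gap. Peaks were on 19 autosomes and the X chromosome, and the Y chromosome was not analysed here. The 21644 protein-coding genes on these chromosomes were used, 1 per symbol, and 24 with a repeated symbol were left out. Each gene had 1 TSS for windows, and all 79264 annotated transcripts gave TSSs for promoters and distances.

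Overlap was counted from 1 bp. Random placements used bedtools 2.31.1 (shuffle), on the same chromosome, without overlaps and outside gaps, with 100 fixed seeds. Bases were assigned to promoter (1 kb on each side of a TSS), then exon, intron and intergenic sequence. Coverage per gene was the percent of bases in peaks within 50 kb of the TSS. Such a window can hold neighbouring genes, so its value need not belong to the named gene. List means were set against 10000 random lists of the same size, matched on the number of protein-coding TSSs in the window, with two-sided permutation p-values and Benjamini-Hochberg adjustment over 19 lists at a threshold of 0.05. Direct differences between lists used two-sided permutation tests over genes with 100000 resamples. Motif density was counted on both strands in peaks more than 2 kb from a TSS and in flanks of the same width 5 kb away, with a pseudocount of 0.5. Its test was a two-sided sign-flip permutation over 19 autosomes with 100000 resamples, adjusted over 14 motifs. Autosomes give a spread but are not biological replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

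The calculations were tested on simulated data. Coverage matched a base by base count in all of 500 windows. On randomly placed peaks over 21644 genes, lists of 24 genes with no planted change were called in 0 of 40 trials. Lists planted at 1.5 times were called in 36 of 40 and lists planted at 2.5 times in 40 of 40. These shares do not give the power on the real peaks. There, random lists matched to the 24 neural progenitor genes had a 95% range of 2.75% to 8.02% around a mean of 5.02%. A list at 1.5 times that mean lies inside this range. The scan of all 14 motifs matched an independent search, and a motif ratio planted at 2 was recovered as 2.13.

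Gene lists, motifs, tests and most alternatives were fixed before the data were examined. The rule for named genes was fixed as well: the 3 highest and 2 lowest members of each list in coverage, every Hox gene, the nearest protein-coding gene of the 20 domains with the most covered bases and the 10 highest genes genome-wide. Alternatives were the pooled list, each replicate alone, peaks with −log10 q of at least 3, peaks with fold enrichment of at least 3, other windows (20 kb, or the gene body with 5 kb on each side), the number of peaks, no matching or matching also on gene length, other flanks, sequence without soft-masked repeats, and merge distances of 1 and 12.5 kb. Alternatives added after the data were seen were peaks that overlapped both replicates' lists, matching on GC content or on repeat content, CpG-matched shuffled motif controls and autosomal genes only. Matching on GC or repeat content replaced the matching on TSS number and was not added to it.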

Results

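Histone H3 monomethylated at lysine 4 (H3K4me1), a chromatin mark found at enhancers and beside promoters, was mapped by chromatin immunoprecipitation and sequencing in hindbrain of mouse embryos at 12.5 days. The hindbrain gives rise to the medulla, the pons and the cerebellum. The design held 1 group with 2 biological replicates, made from pools of 120 embryos (replicate 1) and 88 embryos (replicate 2), so the comparisons are between the replicates and between parts of the genome. The data were 4 peak lists on the mm10 build: 1 per replicate, 1 called on both replicates pooled, and the authors' replicated list. The number of reads behind each list was not given in the files used here, so the depth is unknown. With 1 group there was no second condition to test against. P-values below describe genes, chromosomes or random placements within this peak set and say nothing about animals.

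The replicated list held 129999 peaks that covered 90.3 Mb, which is 3.53% of the sequence without gaps. Its median peak width was 493 bp (interquartile range 318 to 831), and 5153 peaks were wider than 2 kb. The authors' fold enrichment over control ran from 1.53 to 10.2, with a median of 2.98. Replicate 1 alone had 214940 peaks over 98.6 Mb, and replicate 2 alone had 153139 peaks over 64.9 Mb. Peaks with a q-value above 0.05 made up 5.405% of the list of replicate 1, 14.9% of that of replicate 2 and 0.84% of the replicated list.

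The first question was how far both replicates marked the same regions. Around the 21644 protein-coding genes, the amounts of marking went closely together. The percent of bases in peaks within 50 kb of the TSS correlated between replicates (Pearson r 0.984, Spearman rho 0.983). This correlation is across genes, which are not independent replicates. It compares amounts within windows and not the positions of peaks, which the overlaps below measure. Mean coverage was 6.50% in replicate 1 and 4.56% in replicate 2, a ratio of 1.42. Around Notch1, a receptor that keeps neural progenitors undifferentiated, 46.2% of bases lay in peaks of replicate 1 and 37.7% in peaks of replicate 2. Around Gbx2, which positions the midbrain-hindbrain boundary, the values were 25.8% and 17.1%.

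Of the peaks of replicate 1, 51.3% (110171) overlapped a peak of replicate 2 by at least 1 bp. Of the peaks of replicate 2, 79.4% (121644) overlapped a peak of replicate 1. Placing the peaks of replicate 2 at random on the same chromosomes 100 times gave 5.74% (range 5.61 to 5.86) and 7.26% (range 7.09 to 7.39). The base-pair Jaccard index was 43.5%, against 1.75% at random. Overlap was higher among peaks with high fold enrichment. In the lowest decile of replicate 1 it was 25.4% and in the highest 97.6%, and in replicate 2 it was 66.8% and 99.5%.

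**Figure D1:**
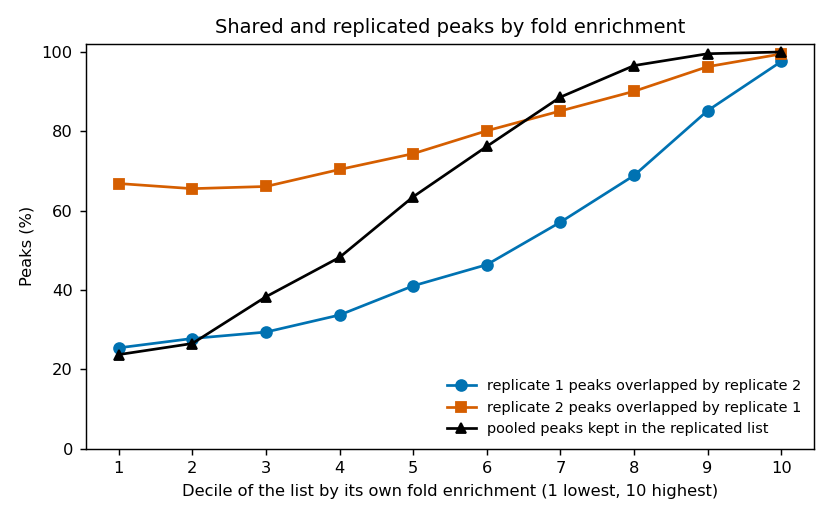
Percent of peaks (vertical axis) that overlapped the other replicate, or that were kept in the replicated list, by decile of each list's own fold enrichment (horizontal axis, 1 lowest and 10 highest). In the highest decile the shares were 97.6% for replicate 1, 99.5% for replicate 2 and 99.98% for pooled peaks.

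The authors' replicated list kept 66.1% (129999) of the 196612 pooled peaks, with identical coordinates. The share kept was 23.7% in the lowest decile of pooled fold enrichment and 99.98% in the highest. Of the replicated peaks, 93.8% overlapped a peak of replicate 1, 79.2% a peak of replicate 2, and 74.5% (96810) a peak of each. These 96810 peaks held 87.3% of the replicated bases. Another 26986 replicated peaks (20.8%) overlapped no peak of replicate 2, and 8043 (6.19%) overlapped none of replicate 1. Of the replicated peaks, 1840 overlapped neither replicate's list. The list therefore also holds peaks absent from the replicate lists used here. Per the labels, the list derives from the pooled list and both replicates' lists. All 95823 pooled peaks whose overlap with a peak of each replicate was at least 50% of either peak were kept. What kept the other replicated peaks, such as a comparison with more relaxed calls, is unknown. A missing overlap therefore does not show that a replicate lacked the mark.

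Where the mark lay relative to genes was measured next. H3K4me1 peaks were concentrated in and near genes: 16.1% of the replicated bases were in promoters (within 1 kb of a TSS), 3.54 times the random share of 4.55%. Introns held 56.8% (1.33 times random) and exons 4.46% (1.41 times). Intergenic sequence held 22.7%, which was 0.456 times the random share of 49.6%. Most peaks were nevertheless distal: 73.1% (94969) lay more than 2 kb from any TSS, against 90.1% at random. Each of these values lay outside all 100 random placements (two-sided permutation p = 0.0099, the smallest that 100 placements can give). Promoters held 14.9% of the bases of replicate 1 alone and 16.2% of those of replicate 2 alone.

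Around TSSs the mark flanked the start site. A replicated peak covered the TSS itself at 13.8% of protein-coding genes. Upstream the share reached 22.4% at 600 bp, and downstream it reached 36.3% at 1000 bp. At 10 kb it was 4.45% upstream and 5.70% downstream. The share at the TSS was 0.381 times that at the downstream maximum, and the replicates gave 0.407 (replicate 1) and 0.336 (replicate 2), with an SD of 0.0505 (n = 2).

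**Figure D2:**
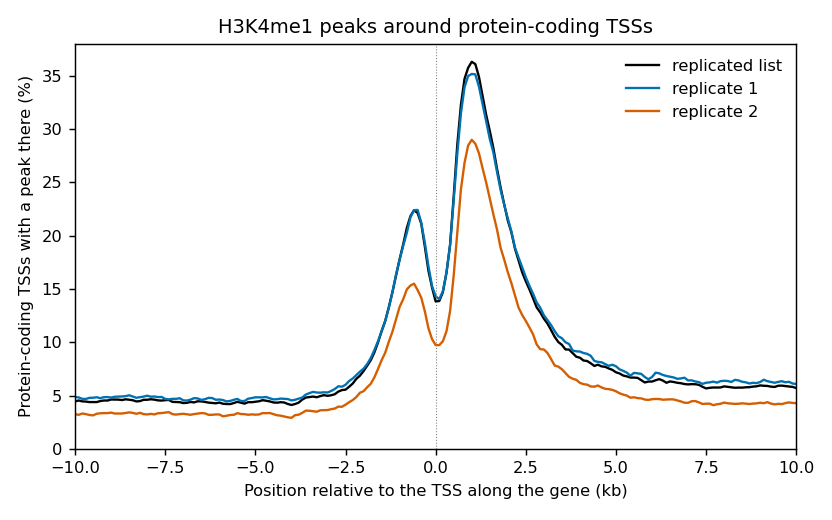
Percent of protein-coding TSSs with a peak at each position (vertical axis) from 10 kb upstream to 10 kb downstream along the gene (horizontal axis, kb), for the replicated list and each replicate. In the replicated list the share was 13.8% at the TSS and 36.3% at 1000 bp downstream.

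The next comparison asked which kinds of genes carried H3K4me1 nearby. By coverage within 50 kb of the TSS, genes of neural progenitors, hindbrain regionalisation and patterning signals were the most densely marked of the 19 gene lists. Other measures gave another order: over the gene body with 5 kb on each side, dorsoventral regulators (23.4%) came before patterning signal genes (23.1%). Within 50 kb of the TSS, peaks covered 14.6% ± 10.3 (SD over genes, n = 24) of bases around neural progenitor genes, 14.4% ± 6.90 (n = 27) around hindbrain and isthmus regulators and 13.04% ± 8.41 (n = 36) around patterning signal genes. These were 2.92, 2.85 and 2.63 times the means of random genes matched on the number of TSSs in the window. Pan-neuronal genes reached 10.6% ± 8.91 (n = 31, 2.17 times) and dorsoventral regulators of hindbrain 10.1% ± 7.20 (n = 36, 2.08 times). For each of these 5 lists no random list of 10000 was as far from the matched mean (two-sided permutation p = 1e-04, the smallest possible, Benjamini-Hochberg adjusted p = 3.2e-04 over 19 lists). The size of the ratios depended on the comparison genes. Matched on repeat content, the first 3 lists were at 1.64, 1.52 and 1.48 times, and matched on GC content at 2.12, 2.20 and 1.51 times, past the threshold in each case. Here and below, these matchings replaced the one on TSS number, so the changes do not isolate repeat or GC content.

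All 27 hindbrain and isthmus regulators were above the median of matched genes. The highest were Pbx1, a cofactor of Hox proteins, at 28.8%, Gbx2 at 26.4% and the guidance receptor gene Epha4 at 25.7%. The lowest were En1, a regulator of the midbrain-hindbrain boundary, at 5.70% and Cnpy1 at 3.66%. Among 24 neural progenitor genes, 23 were above the matched median. Notch1 reached 46.1%, Nes, which encodes the progenitor filament nestin, 34.7% and the Notch target Hes5 22.5%. The lowest were Slc1a3 at 2.94% and Sox3, on the X chromosome, at 0.847%. Of 36 patterning signal genes, 33 were above the matched median, led by the receptor gene Fgfr2 at 30.0%, the Hedgehog receptor gene Ptch1 at 28.8% and the Wnt target Axin2 at 28.3%.

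Of the dorsoventral regulators, which specify progenitor domains and neuron classes, 34 of 36 were above the matched median. Lmx1b reached 32.1%, Pax7 28.2% and Skor1 25.3%, while Dbx1 had 1.89% and Isl1 1.20%. Of the pan-neuronal genes, 27 of 31 were above it. The transcription factor genes Ebf3 (37.1%), Nhlh1 (30.9%) and Ebf1 (25.2%) were the highest, and Stmn2 (0.787%) and the synaptic gene Syt1 (0.702%) the lowest. The calls for these 2 lists depended on the comparison genes. Matched on repeat content, the differences were 2.22 and 2.37 percentage points, with adjusted permutation p = 0.155 for each. Matched on GC content, the dorsoventral difference went from 5.23 to 2.56 percentage points (1.34 times, permutation adjusted p = 0.0123), and the pan-neuronal one from 5.70 to 6.42.

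Ribosomal protein genes, used by all cells, averaged 11.5% ± 8.03 (n = 30), 1.56 times matched genes (permutation adjusted p = 0.00624), with Rps14 at 27.8% and Rpl15 at 1.80%. Matched on GC content, their difference went from 4.13 to 1.45 percentage points (permutation adjusted p = 0.246). Matched on repeat content, it went to 5.98 percentage points (2.08 times, permutation adjusted p = 9.5e-04), a higher ratio than those of the neural lists. The 1461 olfactory and vomeronasal receptor genes, which act in sensory neurons of the nose, were at the other end with 0.224% ± 0.922, 0.0312 times matched genes (adjusted permutation p = 3.2e-04). This ratio was 0.144 when matched on repeat content and 0.226 when matched on GC content. The random lists could hold receptor genes themselves, so part of this rise may be built in. No peak lay within 50 kb of the TSS for 1290 of them, among them Vmn2r98, and Olfr221 had the highest value at 15.6%.

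The remaining 12 lists did not pass the threshold. Lists of cells that a dissected hindbrain could also contain were near their matched genes: choroid plexus 5.37% (1.03 times), oligodendrocyte and myelin 6.80% (1.11 times), endothelial and pericyte 6.31% (1.19 times), meningeal and mesenchymal 5.94% (1.20 times) and blood and microglia 7.30% (1.08 times). Windows of single members stood higher, such as those of Lyl1 at 46.0%, Prrx2 at 23.9%, Eng at 21.3% and the myelin gene Mbp at 18.9%. These windows can also hold neighbouring genes. Whether the peaks in them belong to the named genes was not tested, so the values do not show marking of blood, mesenchymal, vessel or myelin genes. No replicated peak lay within 50 kb of Itgam, Trem2, Lum or Tek. For tissues outside the brain, skeletal muscle and heart genes had 8.34% (1.35 times), germline genes 4.86% (0.822 times) and liver and gut genes 3.60% (0.603 times), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had none. Adjusted permutation p-values of these 8 lists ran from 0.157 to 0.938.

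**Figure D3:**
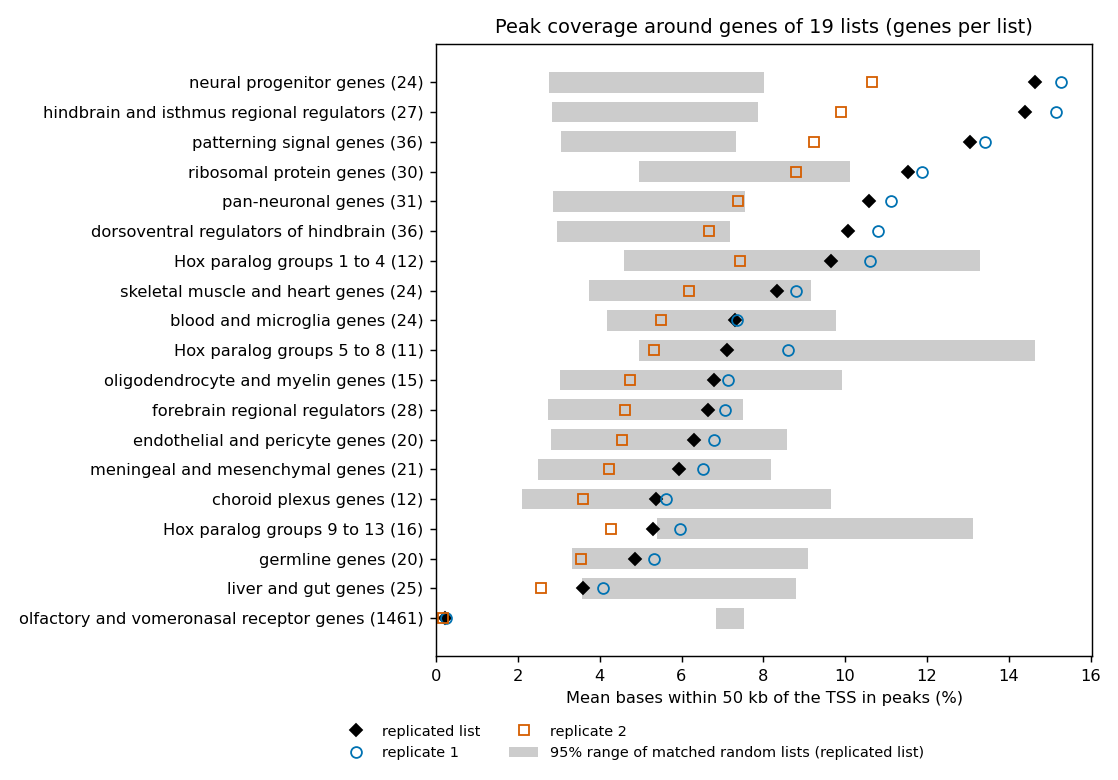
Mean percent of bases in peaks within 50 kb of the TSS (horizontal axis) for 19 gene lists, with the number of genes in brackets. Diamonds are the replicated list, open symbols each replicate, and grey bars the 95% range of random lists matched on TSS number, which apply to the diamonds. Neural progenitor genes (14.6%) and hindbrain and isthmus regulators (14.4%) were highest and olfactory and vomeronasal receptor genes (0.224%) lowest.

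A direct test asked whether regulators of the sampled region were marked more than those of another brain region. Hindbrain and isthmus regulators had 14.4% ± 6.90 (n = 27) and forebrain regulators 6.66% ± 6.55 (n = 28), a difference of 7.73 percentage points (two-sided permutation test, 100000 resamples, p = 5e-05). The difference was 8.10 in replicate 1 alone and 5.27 in replicate 2 alone. Whether members of either list are used in both regions was not tested. The difference is thus one between these lists and does not isolate region. Among forebrain regulators, Bcl11b, which is also used in other neurons, had 37.2%, Eomes 11.3% and Emx1 10.8%. Nkx2-1, a regulator of ventral forebrain, had 0.887% and Arx 1.34%. As a list, forebrain regulators were 1.39 times their matched genes (permutation adjusted p = 0.213). The list passed the threshold in a 20 kb window (adjusted permutation p = 0.0237). It also passed over the gene body with 5 kb on each side (2.72 times, adjusted permutation p = 2.7e-04). Matched on repeat content it was at 0.840 times (adjusted permutation p = 0.441). Above the matched median were 24 of 28 forebrain regulators, 21 of 24 skeletal muscle and heart genes and 16 of 21 meningeal and mesenchymal genes, without a test between these shares.

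Hox genes pattern the body axis, and the hindbrain expresses members of the anterior paralog groups. Peaks covered 14.2% ± 8.70 (n = 12) of the bodies of Hox genes of groups 1 to 4 with 2 kb on each side, 8.76% ± 5.67 (n = 11) in groups 5 to 8 and 6.70% ± 6.06 (n = 16) in groups 9 to 13. Hoxa1 had 28.2%, Hoxb2 26.1% and Hoxd1 25.5%, whereas Hoxa10, Hoxb13, Hoxc11 and Hoxc12 had none in the replicated list. Hoxd13 at 20.2%, Hoxd9 at 14.4% and Hoxa13 at 13.2% were the largest exceptions among posterior genes, and Hoxa2 (4.58%), Hoxd4 (4.29%) and Hoxc4 (4.14%) among anterior ones. The difference between groups 1 to 4 and groups 9 to 13 was 7.54 percentage points (two-sided permutation test over genes, p = 0.0116). By cluster, the means of these groups were 15.9% and 6.25% in Hoxa and 16.5% and 4.50% in Hoxb, but 12.4% and 10.3% in Hoxd, and 4.14% (1 gene) and 4.31% in Hoxc. No test between clusters was run, and the Hoxa means were 12.8% and 8.02% in replicate 1 alone and 13.2% and 5.87% in replicate 2 alone. The difference over all clusters did not pass the threshold with peaks of −log10 q of at least 3 (permutation p = 0.0541), with fold enrichment of at least 3 (2.71 percentage points, permutation p = 0.216), with the gene body alone (permutation p = 0.0708) or with peaks that overlapped both replicates' lists (4.61 percentage points, permutation p = 0.0804). Within 50 kb of the TSS, against matched genes, Hox genes were at 1.12 (groups 1 to 4), 0.745 (groups 5 to 8) and 0.588 times (groups 9 to 13), and none passed the threshold (permutation adjusted p = 0.735, 0.5001 and 0.142). Neighbouring Hox genes share sequence windows and are not independent.

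**Figure D4:**
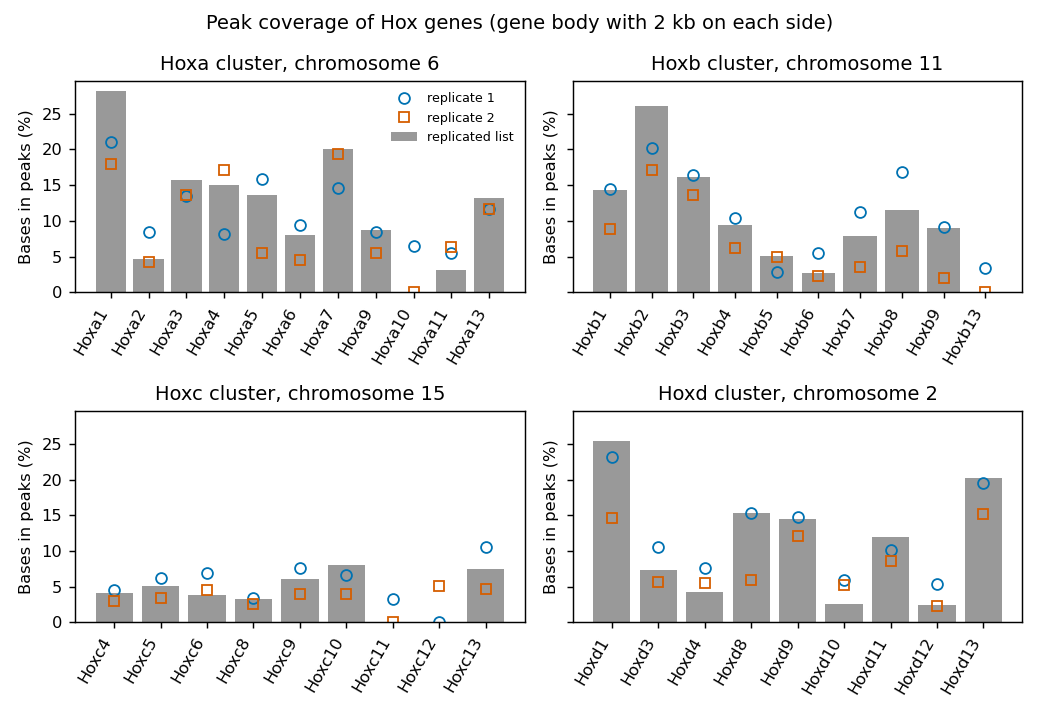
Percent of bases in peaks (vertical axis) over the body of each Hox gene with 2 kb on each side, by cluster and in paralog order. Bars are the replicated list and open symbols each replicate. Hoxa1 (28.2%), Hoxb2 (26.1%) and Hoxd1 (25.5%) were the highest of the anterior genes, and Hoxd13 (20.2%) of the posterior ones.

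Sequence motifs in distal peaks were compared with flanking sequence. Motifs of some transcription factor families were denser in peaks. The RFX motif was 4.36 ± 1.43 times (mean and SD over 19 autosomes) as dense in peaks as in flanks, and the proneural bHLH E-box 1.54 ± 0.0536 times. Distal peaks on autosomes numbered 94573 over 61.5 Mb and had a GC content of 50.3%, against 45.1% in flanks. Each ratio was therefore set against that of the same consensus read backwards. Relative to this control the RFX motif was 4.09 times, the NFI motif 3.49 times (153 sites) and the E-box 2.14 times as dense, higher on 16, 16 and 19 of the 19 autosomes (sign-flip permutation, adjusted p = 3.8e-04, 9.3e-05 and 4.7e-05). The POU octamer was 1.55 times, MEF2 1.38 times, HOX-PBX 1.28 times, the homeodomain core 1.15 times, SOX 1.09 times and GATA 1.07 times the control, with adjusted permutation p from 4.7e-05 to 0.00745. Of these, MEF2 (0.955 times), HOX-PBX (0.865), the homeodomain core (0.860) and GATA (0.858) were less dense in peaks than in flanks, and stood higher only relative to their control.

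HNF1, HNF4, ETS, PU.1 and CTCF motifs did not pass the threshold, at 1.44, 0.980, 1.09, 0.908 and 1.03 times the control. The size of the E-box and homeodomain values depended on the control. Against shuffled sequences with the same number of CpG dinucleotides, the E-box was 1.38 times and the homeodomain core 1.97 times as dense, the latter with shuffled sequences at 0.437 times their own density in flanks. With that control GATA did not pass the threshold, at 1.03 times (permutation adjusted p = 0.115). CTCF at 0.728, HNF4 at 1.21 and HNF1 at 1.81 times the control then passed it (permutation adjusted p = 0.00118, 6.4e-04 and 0.00275). For CTCF and HNF4 the direction was opposite to the main analysis. Without a control, CTCF was denser in peaks than in flanks (8.18 and 7.36 sites per Mb) and HNF4 less dense (12.6 and 14.7). CTCF was thus lower, and HNF4 higher, only relative to this control. HNF1 rested on 35 sites, at 0.570 per Mb in peaks and 0.786 in flanks, with a mean ratio over autosomes of 1.05.

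**Figure D5:**
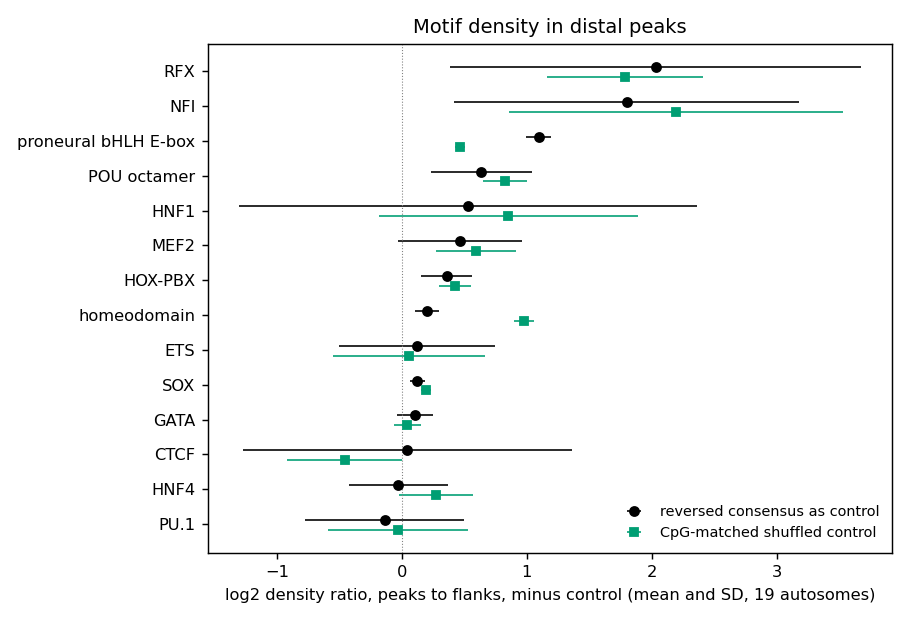
Log2 ratio of motif density in distal peaks to flanks minus that of the control (horizontal axis, mean and SD over 19 autosomes) for 14 motifs. Circles use the reversed consensus as control and squares the CpG-matched shuffled sequences. The RFX motif was at 2.03 and 1.79, and the E-box at 1.10 and 0.47.

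The largest domains of H3K4me1 were described last, ranked by the bases that peaks covered and not by the distance from end to end. Merging replicated peaks within 3 kb gave 60151 domains, of which 663 covered more than 10 kb. The largest lay over Gse1, on chromosome 8 from 120322077 to 120576782, with 193 kb covered by 91 peaks (191 kb in replicate 1 and 163 kb in replicate 2). Next were Ephb2, a guidance receptor gene, with 89.1 kb, Ssbp3, which encodes a partner of LIM-homeodomain complexes, with 82.4 kb, and Msi2, a neural progenitor RNA-binding protein gene, with 69.6 kb and a neighbouring domain of 62.4 kb. Ccdc85c (61.5 kb), Zmiz1 (61.4 kb), Ncor2 (57.1 kb) and Tcf20 (53.0 kb) followed. All 20 of the largest domains overlapped a protein-coding gene. These included the corepressor genes Ncor2 and Tle3, the nuclear receptor gene Rara, the zinc finger genes Zfp423 and Casz1, and the DNA demethylase gene Tet3. Map4k4, Macrod1, Dab2ip, Fyn and Pmepa1, outside these classes, were also among them. No test of gene classes was run.

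Ranked by the share of bases within 50 kb of the TSS, the highest genes genome-wide were Gse1 at 79.3%, Ccdc85c at 58.5%, Flrt1 at 57.4%, Pipox at 54.8%, Ncor2 at 54.3%, Bahcc1 at 51.6%, Ssbp3 at 51.0%, Ephb2 at 50.2%, Tle3 at 49.4% and Cxxc5 at 49.1%. The ranking of domains depended on the merge distance: 11 of the 20 were shared at 1 kb and 9 at 12.5 kb.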

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

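The comparisons on peaks overlapping both replicates' lists, matched on GC or repeat content, with CpG-matched controls or on autosomal genes only were chosen after the data were seen. Of 496 alternative values for 48 results, 409 kept their direction and side of the threshold or stayed within a tolerance, and 44 reversed direction. The tolerance differed by result, such as a binomial interval over peaks, the SD of the replicates or a fixed factor for counts of lists. Of these 44, 0 came from a main value past the threshold and 2 passed it after reversing. The cause of the changes below was not tested. Leaving out a replicate could not be run for the overlap of replicates or for the share of pooled peaks kept, which need both.

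For replicate 1, replicate 2 and the Jaccard index, overlap was 42.1%, 85.2% and 40.8% with −log10 q of at least 3, 56.5%, 69.8% and 44.2% with fold enrichment of at least 3, and 61.0%, 70.2% and 45.9% with equal numbers of peaks. Asking that at least 50% of a peak be covered gave 38.6% and 70.8%. With −log10 q of at least 3, 86.8% of pooled peaks were kept. The ratio of the TSS to its flank was 0.321 with fold enrichment of at least 3.

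For gene lists, differences from matched genes are in percentage points. Forebrain regulators passed the threshold at 4.13 (20 kb window), 11.12 (gene body) and 2.67 (matched on gene length). Hox groups 9 to 13 passed at -4.25 (fold enrichment of at least 3), -5.16 (GC) and -6.18 (repeats), Hox groups 5 to 8 at -6.01 (GC), liver and gut genes at -3.30 (GC) and -4.33 (repeats), and germline genes at -5.98 (gene body). Hox groups 1 to 4 passed by number of peaks, with 7.15 more than matched genes. Ribosomal protein genes no longer passed at 1.45 (GC), nor dorsoventral regulators at 2.22 and pan-neuronal genes at 2.37 (repeats). Lists below their matched genes and past the threshold numbered 2 with fold enrichment of at least 3, 2 with the gene body, 4 with GC and 3 with repeats, against 1.

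The reversed differences that follow were not past the threshold, in the main analysis or after. Choroid plexus genes (main 0.165) were at -0.0469 (−log10 q), -0.0883 (fold enrichment), -0.264 (peaks overlapping both replicates' lists), -0.208 (20 kb), -0.760 (no matching), -2.54 (GC), -2.97 (repeats) and -0.144 (autosomes), and from -0.198 to 0.0535 with either replicate left out. Hox groups 1 to 4 (1.06) were at -1.78 (fold enrichment), -0.685 (peaks overlapping both replicates' lists), -0.751 (GC) and -1.36 (repeats). Oligodendrocyte genes (0.695) were at -0.0788 (fold enrichment), -1.27 (GC) and -1.34 (repeats). Blood genes (0.542) were at -1.10 (20 kb), -2.41 (gene body), -0.894 (number of peaks) and -1.69 (GC). Meningeal genes (1.01) were at -0.227 (no matching), -0.293 (GC) and -2.18 (repeats), endothelial genes (1.00) at -0.416 (GC) and -2.16 (repeats), and muscle and heart genes (2.17) at -2.25 (GC) and -0.888 (repeats). Forebrain regulators (1.85) were at -1.27 (repeats). Hox groups 5 to 8 (-2.44) were at 2.82 (number of peaks) and 0.932 (no matching), and germline genes (-1.06) at 0.258 (number of peaks).

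The difference between Hox groups 1 to 4 and 9 to 13 missed the threshold at 5.55 (−log10 q of at least 3), 2.71 (fold enrichment of at least 3), 4.61 (peaks overlapping both replicates' lists) and 7.91 (gene body). The 20 domains with the most covered bases shared 11 at a merge distance of 1 kb, 9 at 12.5 kb, 13 with the pooled list, and 13 to 17 with either replicate alone. With CpG-matched controls, log2 values relative to the control were -0.46 for CTCF and 0.27 for HNF4, both reversed, and 0.85 for HNF1. All of these were then past the threshold. GATA, at 0.044, was no longer past the threshold. GATA was at 0.027 without soft-masked bases and MEF2 at 0.39 with fold enrichment of at least 3, both not past it. Reversed and not past the threshold were CTCF (main 0.045) at -0.26 (pooled list), -0.25 (−log10 q), -0.37 (fold enrichment) and -0.15 (peaks overlapping both replicates' lists), and from -0.192 to -0.186 with either replicate left out. So were HNF4 (-0.028) at 0.12 (flanks 10 kb away), and ETS (0.12) at -0.100 and PU.1 (-0.14) at 0.10 without soft-masked bases. With either replicate left out, HNF4 ran from -0.031 to 0.0079 and ETS from -0.015 to 0.17. No paired analysis was possible because there is 1 group.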

Other observations

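The tests of TSSs inside peaks, of replicate 1's own fold enrichment and of the X chromosome were chosen only after the result was seen, as were the comparisons matched on GC or repeat content, whose criteria were written before those matched values were computed.

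Peaks lay over the start site itself more often than in matched genes in several lists. Of 28 forebrain regulators, 14 (50%) had the TSS inside a replicated peak, 3.54 times the 14.1% of matched genes, although their 50 kb windows did not pass the threshold. Dorsoventral regulators, whose windows did pass it, had 63.9% (23 of 36, 4.45 times), meningeal and mesenchymal genes 57.1% (12 of 21), endothelial and pericyte genes 55% (11 of 20) and skeletal muscle and heart genes 45.8% (11 of 24). Each of these 5 lists had a permutation adjusted p of 3.2e-04. Also above and past the threshold were choroid plexus genes (50%), oligodendrocyte and myelin genes (46.7%) and neural progenitor genes (41.7%). So were Hox groups 1 to 4 (41.7%) and patterning signal genes (36.1%), and these further lists had permutation adjusted p from 0.00271 to 0.0285. Ribosomal protein genes had 3.33% (1 of 30, permutation adjusted p = 0.167), while 100% of them had a peak within 2 kb. Hindbrain and isthmus regulators had 22.2% (6 of 27, permutation adjusted p = 0.354) and pan-neuronal genes 22.6% (7 of 31, permutation adjusted p = 0.385), and these lists were not tested against each other.

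The shares depended on the replicate. In replicate 1 and replicate 2 they were 53.6% and 46.4% for forebrain regulators, 58.3% and 33.3% for dorsoventral regulators and for muscle and heart genes, 57.1% and 23.8% for meningeal genes, and 55% and 35% for endothelial genes. Of the 19 lists, 10 were above matched genes and past the threshold, and 1 was below and past it. Matching was on TSS number only, and no explanation was tested.

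Whether weak enrichment close to the calling threshold accounts for the 26986 replicated peaks (20.8%) without a peak of replicate 2 is open. The share was 43.0% in the lowest decile of pooled fold enrichment and 0.031% in the highest, under the 1% set beforehand, but pooled fold enrichment includes the reads of replicate 2. By replicate 1's own fold enrichment, 2.40% of its highest decile lacked an overlap. Whether one dissection held more blood, vessel, meningeal or choroid plexus cells could not be decided. Over these 4 lists together (77 genes), the log2 ratio of replicate 1 to replicate 2 coverage, relative to matched genes, was 0.0044. The 95% range of random lists was -0.08 to 0.08, and the value stayed inside the limits set beforehand. Single lists ran from -0.080 (blood) to 0.071 (choroid plexus). Their coverage was near that of matched genes (1.03 to 1.20 times), so these windows were not shown to carry signal of such cells. The different number of control files, the unknown depth and a different extent of dissection stay open and were not tested. Of all 19 lists, Hox groups 5 to 8 (0.25, permutation adjusted p = 0.0114) and olfactory and vomeronasal receptor genes (0.13, permutation adjusted p = 0.0019) were relatively higher in replicate 1. Genes are not independent in either list. Coverage around the receptor genes was very low, at 0.243% in replicate 1 and 0.159% in replicate 2.

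Matched on GC content in place of TSS number, 6 of the 7 lists past the threshold stayed past it in the same direction. This lay between the criteria of at most 50% and at least 90% of them set beforehand. The part played by GC content of the windows is therefore open, and it was not separated from that of dropping TSS number. The exception was ribosomal protein genes, whose matched mean rose from 7.41% to 10.1% (difference from 4.13 to 1.45 percentage points), and among the lists kept the dorsoventral difference went from 5.23 to 2.56. For olfactory and vomeronasal receptor genes, 19.1% of the difference stayed under matching on repeat content, which met the criterion of under 50% for repeats and paralogs that reads cannot be placed in. The random lists could hold receptor genes themselves, and how many they held was not counted. A smaller difference under either matching may thus be partly built in, so meeting the criterion does not decide for repeats. The remaining difference of -1.33 percentage points was still past the threshold (permutation adjusted p = 9.5e-04), so repeat content did not remove it all. Matching on GC content left 11.03%, so repeats are not singled out, and GC and repeat content were not separated.

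The X chromosome had few peaks. It held 650 replicated peaks over 0.202% of its sequence, against 3.78% ± 0.960 (SD) over 19 autosomes, and Sox3, Arx and Plp1 on it were among the lowest of their lists. Fewer protein-coding genes do not account for this, since X had 0.686 peaks per gene, 0.171 times the lowest autosome. A copy number of 0.75 in a pool of both sexes was applied to autosomal fold enrichment with a minimum of 3.5. It predicted 7.02 times the X peaks per gene, relative to autosomes, that were observed above that minimum (63 X peaks). The value was 4.43 at a minimum of 3 (210 X peaks) and 11.8 at 4 (17 X peaks). At 3.5 it was 4.99 in replicate 1 and 4.92 in replicate 2, so the tables argue against that scaling alone. A scale of 0.5 stands for 1 marked X chromosome per cell against 2 copies of each autosome. With it the prediction was 0.304 times the observed value at 3.5, 0.406 at 3 and 0.207 at 4. The observed value thus lay between the predictions of the 2 scales. Fewer marked X chromosomes per cell stay open, with no test beyond this scaling, and filtering by the authors stays open and untested.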
